A study of Homo sapiens with 7 samples.

How the data were processed

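The 7 libraries were made from cells crosslinked with 1% formaldehyde, per the labels' protocols, and each library gave 1 peak list. Per the submitters' processing notes, FastQC 0.11.9, BWA 0.7.17-r1188, SAMtools 1.9 and MACS2 2.1.4 were used with build hg19. The notes name no roles or settings, and the threshold and any input control are not given in the sources used here. The deposited files hold 1 score per peak, a whole number that is the authors' own value for that peak. The score's definition is not given, so scores were used only to describe, rank or filter peaks within a list. The lowest score was 13 in the 22Rv1 lists and between 40 and 48 in the LNCaP lists, so the lists did not share a floor. All 65461 peak names of the list labelled vehicle FOXA1 carry the tag siNTC, which the labels do not mention, so it is called vehicle only as labelled.

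Groups were taken from the sample titles, with 1 library per group, so neither spread between replicates nor a test between conditions was available. Read depth is not in the lists, and peak number depends on depth and enrichment. Peaks on chromosomes 1 to 22, X and Y were used. A peak was shared when it overlapped a peak of the other list by at least 1 bp. Percentages have 95% Wilson intervals for counting error only. Expected overlaps came from 100 placements of each list on the same chromosomes with bedtools 2.31.1, and, added after the data were examined, from 100 shifts of each peak by 10 kb to 1 Mb. FOXA1 loss was the share of shCTL peaks with no shSETD7 peak, gain the reverse. Each was compared between peaks at SETD7 sites and others within 10 score groups, with intervals from 2000 resamplings within groups.

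Merged sites of the LNCaP lists were counted by pattern, for the lists as deposited and for equal-sized lists. Unchanged LNCaP libraries were simulated as a strength per candidate site plus noise, set so that DMSO peaks were kept in the combination as often as observed, and, added after the data were examined, with more noise for GSK2879552. Steps along chromosomes were searched in 2 Mb windows with at least 20 Mb on each side, and ratios were correlated over 10 Mb windows with at least 50 peaks in the control lists. A step is the log2 ratio before the position minus that after it. Unchanged window counts were simulated as Poisson draws at the mean rate of each window, independent of score, 100 times. The chromosome set, the steps and the windows were chosen after the data were examined. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

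The overlap code gave the same 37413 shared shCTL peaks as bedtools. On simulated data, a loss difference of −10 points was recovered as −9.82 over 2074 peaks, and a step of −1 (log2) on chromosome 3 as −1.02 over 6998 peaks. The named sites were fixed before the data were examined as the highest scores of each class: 10 SETD7 peaks, 10 such peaks at vehicle FOXA1 peaks (the same 10), 10 in each direction of the knockdown and GSK2879552 comparisons, and 5 DMSO and GSK2879552 sites without the combination. Alternatives were other overlap rules, the higher-scoring 50% of each list, equal-sized lists, the shCTL list for the SETD7 overlap, and loss and gain without score matching. Promoter shares, motif content and peak counts near gene lists had been planned. They needed an hg19 annotation or sequence, which was not used here, so sites are given by position without gene names.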

Results

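Chromatin immunoprecipitation sequencing was used to map SETD7, a lysine methyltransferase, and FOXA1, a forkhead pioneer transcription factor, in 22Rv1 (CWR22-Rv1 in the labels) and LNCaP cells, established human prostate cancer lines. The series holds 7 libraries, with 1 library in each group, and each is represented by the authors' own peak list on build hg19. In 22Rv1, SETD7 was mapped in vehicle cells (25526 peaks). FOXA1 was mapped in vehicle cells (65461 peaks), in cells with a control hairpin, shCTL (83994 peaks), and in cells with a hairpin against SETD7, shSETD7 (63952 peaks). In LNCaP, FOXA1 was mapped after 4 hours with DMSO (80205 peaks), with GSK2879552, an inhibitor of the lysine demethylase LSD1 (64217 peaks), or with GSK2879552 plus PFI-2, an inhibitor of SETD7 (83833 peaks). Read depth is unknown from peak lists, and without replicates no difference between conditions was tested. The 95% Wilson intervals given with percentages cover counting error only.

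SETD7 peaks were concentrated on 5 chromosomes. Chromosomes 1, 3, 7, 8 and 12, picked after the counts were seen, held 69.8% of the SETD7 peaks (69.2 to 70.4). They held 40.2% of the vehicle FOXA1 peaks (39.8 to 40.6) from the same line and 31.9% of the LNCaP DMSO FOXA1 peaks (31.6 to 32.2). On chromosome 1, SETD7 peaks numbered 3.53 per Mb before position 120 Mb and 37.5 per Mb after it. Vehicle FOXA1 peaks also rose across this position, from 20.8 to 33.4 per Mb, while LNCaP DMSO FOXA1 peaks went from 29.2 to 26.2 per Mb. The 10 SETD7 peaks with the highest scores were led by chromosome 1 from 121484090 to 121485424 and chromosome 7 from 61968575 to 61970591. They overlapped a peak in all 7 lists, whichever the antibody or line, so they were not particular to SETD7. Their scores were 14275 to 116716, against a median of 28 in the SETD7 list. No artefact-prone regions were removed here, so signal unrelated to either protein was not excluded at these sites.

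**Figure D1:**
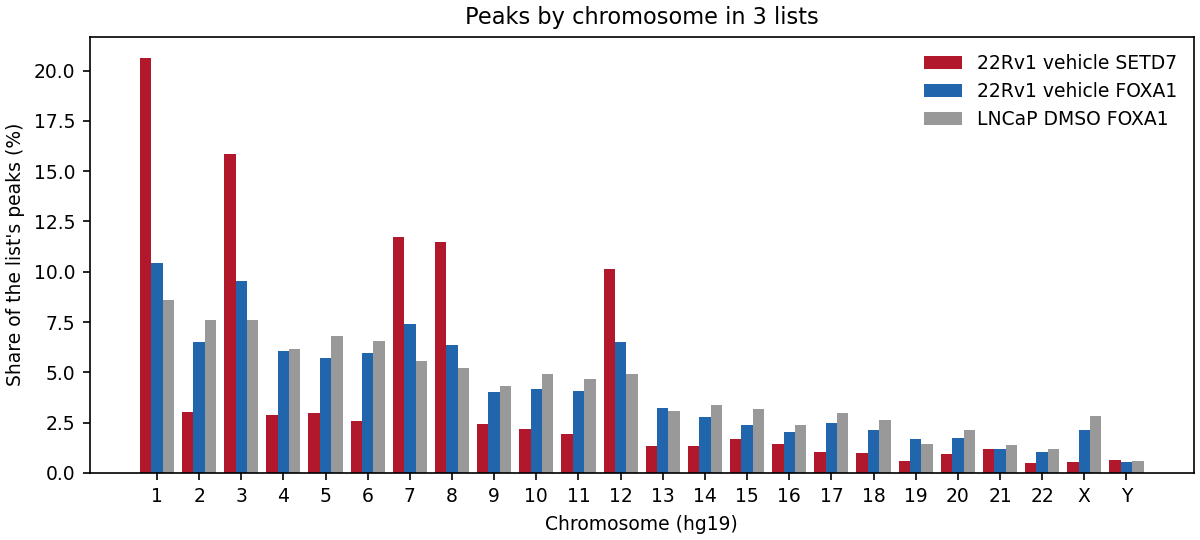
Share of each list's peaks (%, vertical axis) on each chromosome (horizontal axis) for SETD7 and FOXA1 in 22Rv1 vehicle cells and FOXA1 in LNCaP cells with DMSO, 1 library each and no error bars. Chromosomes 1, 3, 7, 8 and 12 together held 69.8% of the SETD7 peaks, against 31.9% of the LNCaP peaks.

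The SETD7 and FOXA1 lists of vehicle 22Rv1 cells were compared to ask how often both proteins were found at the same site. Of the SETD7 peaks, 1497 overlapped a vehicle FOXA1 peak, or 5.86% (5.58 to 6.16). Random placement on the same chromosome gave 1.73% on average, and shifting each peak by up to 1 Mb gave 2.01%. In the highest decile of SETD7 scores 24.8% overlapped FOXA1 (23.1 to 26.5), and in the lowest decile 3.13% (2.53 to 3.88). Below the highest decile the share with vehicle FOXA1 changed little, and no decile exceeded 4.58%. With the other 22Rv1 lists it was higher in decile 9 than in the lowest decile, at 6.97% against 3.49% for shCTL and 17.2% against 8.62% for shSETD7. With LNCaP DMSO FOXA1 the highest and lowest deciles gave 10.7% (9.55 to 12) and 1.57% (1.15 to 2.13), so overlap also rose in the highest decile across lines. The highest decile includes the 10 peaks found in all 7 lists, and peaks of that kind were not removed. Its share therefore cannot be read as binding of both proteins alone. Conversely, 2.56% of the vehicle FOXA1 peaks overlapped a SETD7 peak (2.44 to 2.68). The share of SETD7 peaks at FOXA1 peaks was 7.89% with the shCTL list, 15.5% with the shSETD7 list (15.1 to 16.0) and 2.58% with the LNCaP DMSO list (2.39 to 2.78), for which random placement gave 2.05% and local shifts 2.16%. The share with vehicle FOXA1 depended on the SETD7 peaks used: it was 9.34% without chromosomes 1, 3, 7, 8 and 12. It was 14.8% for the 5000 highest SETD7 scores, which include the highest decile. For the higher-scoring 50% of both lists local shifts gave 1.18%, against 2.01% for the whole lists. The share there was 5.60%, inside the interval of 5.58 to 6.16 for the whole lists. It also depended on the overlap rule, with 2.01% for reciprocal 50% overlap (0.653% by local shifts), 3.85% for midpoints within 200 bp (1.21%) and 12% within 1 kb (7.75%).

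The shCTL and shSETD7 lists were compared to ask which FOXA1 sites remained after SETD7 knockdown. Of the shCTL FOXA1 peaks, 44.5% (44.2 to 44.9) overlapped an shSETD7 peak, and 58.2% of the shSETD7 peaks (57.8 to 58.6) overlapped an shCTL peak. The vehicle list, of similar length to the shSETD7 list, overlapped 51.3% of the shCTL peaks (50.9 to 51.6). Much of the absence was thus also seen between lists of cells without the SETD7 hairpin. In the lowest decile of shCTL scores, 19.0% were found in the shSETD7 list and 13.7% in the vehicle list. The loss reached strong sites. In the highest decile of shCTL scores, 1634 of 8400 peaks had no shSETD7 peak within 1 kb, or 19.5% (18.6 to 20.3), and 1478 of these were peaks in vehicle cells. In the other direction, 54 of 6396 peaks in the highest decile of shSETD7 scores had no shCTL peak within 1 kb, or 0.844% (0.648 to 1.1). SETD7 levels after knockdown were not analysed here.

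Among the shCTL sites without an shSETD7 peak within 1 kb, the highest scores were at chromosome 1 from 248618252 to 248618812 (score 14511), from 248799846 to 248800424 (11164) and from 224504961 to 224505530 (10134). All 10 highest such sites were peaks in vehicle cells, and 9 were peaks in LNCaP DMSO cells. Sites of vehicle FOXA1 that were also found in LNCaP with DMSO and with the combination numbered 29768. The shCTL list held 85.0% of them (84.6 to 85.4) and the shSETD7 list 54.1% (53.5 to 54.7). Peaks of the shSETD7 list alone were mostly weak: 82.2% lay in the lower-scoring 50% of that list, 12% were found in vehicle cells and 8.97% overlapped SETD7. The highest score among shSETD7 sites without an shCTL peak within 1 kb was 3756, at chromosome 2 from 116139520 to 116139769.

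**Figure D2:**
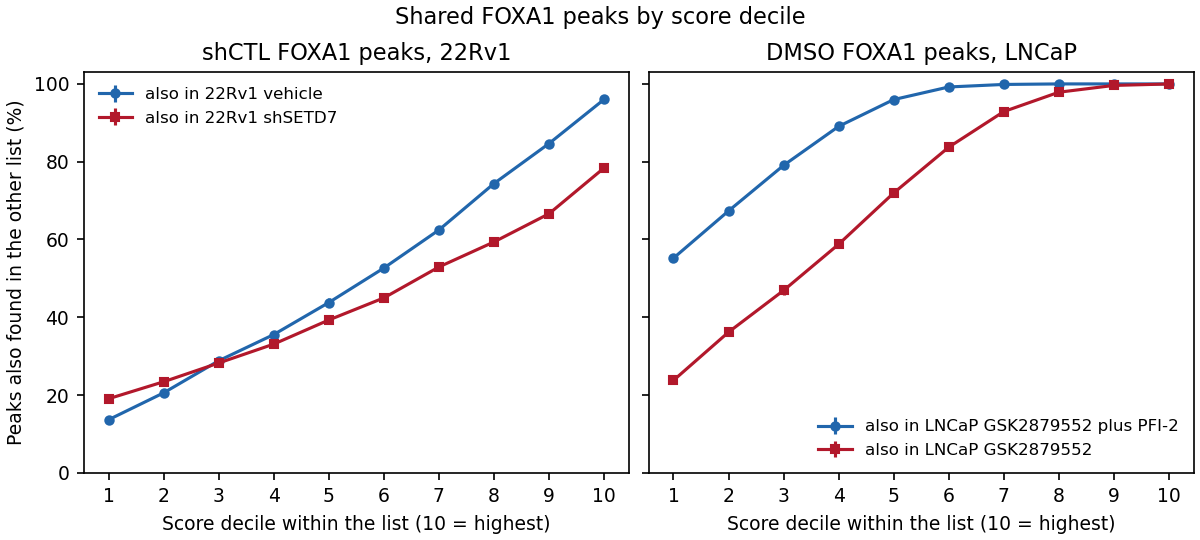
Percent of FOXA1 peaks also found in another list (vertical axis) by decile of the peak score within the list (horizontal axis, 10 highest), for shCTL peaks of 22Rv1 (left) and DMSO peaks of LNCaP (right); bars are 95% Wilson intervals, mostly smaller than the symbols. In the highest decile, 78.4% of shCTL peaks were found in the shSETD7 list and 96.0% in the vehicle list.

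The ratio of shSETD7 to shCTL FOXA1 peak numbers was uneven along chromosomes. On chromosome 3 the log2 ratio of shSETD7 to shCTL peaks was 0.33 before position 78 Mb and −0.42 after it. Before this position the vehicle, shCTL and shSETD7 lists held 2327, 2019 and 2532 peaks, and after it 3909, 4979 and 3715. Against vehicle, the log2 step (before minus after) was −0.55 for shCTL and 0.195 for shSETD7, so it lay mainly in the control list. On chromosome 8 the ratio of shSETD7 to shCTL was −0.96 before 36 Mb and −0.28 after it. These positions were found by a search of 6 ratios on 23 chromosomes. Chromosomes 13 and 21 had steps of similar size, 0.68 (from −0.31 to −0.99) and −0.63 (from −0.77 to −0.14).

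**Figure D3:**
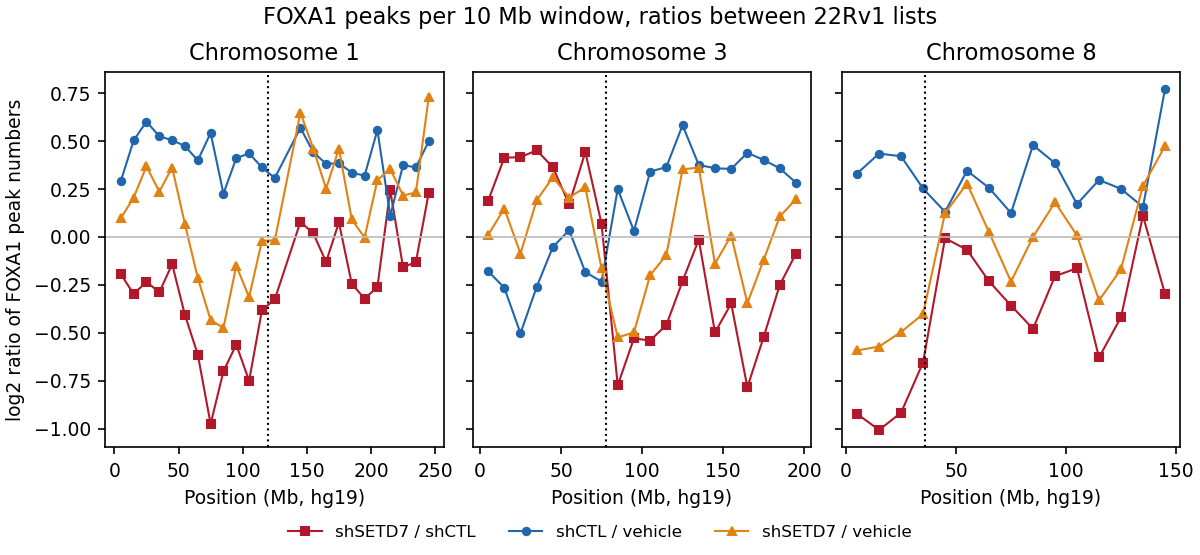
Log2 ratio of FOXA1 peak numbers (vertical axis) in 10 Mb windows along chromosomes 1, 3 and 8 (horizontal axis, Mb) for 3 pairs of 22Rv1 lists, 1 library each, with dotted lines at 120, 78 and 36 Mb. On chromosome 3 the ratio of shSETD7 to shCTL was 0.33 before the line and −0.42 after it.

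Loss and gain of FOXA1 peaks were then set against SETD7 peaks of vehicle cells, with peaks matched by score decile. Of the 2074 shCTL FOXA1 peaks at SETD7 peaks, 28.0% had no shSETD7 peak, against 54.6% of the matched other peaks, a difference of −26.6 percentage points (−28.4 to −24.7, resampling of peaks). Of the 3992 shSETD7 FOXA1 peaks at SETD7 peaks, 60.0% had no shCTL peak, against 48.3% elsewhere, a difference of 11.8 points (10.7 to 13.0). FOXA1 peaks at SETD7 sites were lost less often and gained more often in the library of the knockdown cells. Both differences went with a closer match of the SETD7 peaks to the shSETD7 list. Their overlap was 7.46 times random placement there, against 3.15 for shCTL and 3.40 for vehicle. Of the shSETD7 peaks, 9.40% overlapped SETD7 in the lowest score decile and 5.38% in the highest. Most SETD7 peaks lay near the floor of their list, with a lowest score of 13 and a median of 28. Chromosomes 1, 3, 7, 8 and 12, where SETD7 peaks were concentrated, held 48.1% of the peaks of the shSETD7 list alone. They held 38.1% of the shSETD7 peaks also in the shCTL list. The cause of the closer match was not tested. Without chromosomes 1, 3, 7, 8 and 12 the differences were −19.5 and 7.60 points. With equal-sized lists they were −17.1 and 9.32 points, and without score matching −28.1 and 19.5 points.

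In LNCaP, GSK2879552 was compared with DMSO to ask which FOXA1 sites LSD1 inhibition changed. Of the DMSO peaks, 71.2% (70.9 to 71.5) overlapped a GSK2879552 peak, and 89.6% of the GSK2879552 peaks (89.4 to 89.9) overlapped a DMSO peak. The 23127 DMSO peaks without a GSK2879552 peak were weak ones, 91.0% of them in the lower-scoring 50% of the DMSO list. None of the 8021 peaks in the highest decile of DMSO scores lacked a GSK2879552 peak within 1 kb, and a count of 0 allows a share of up to 0.0374%, taken as 3 peaks of 8021. The GSK2879552 peaks were narrower, with a median width of 263 bp against 333 bp with DMSO and with the combination. The GSK2879552 list was also the shortest: lists of equal size raised the kept share to 81.4%.

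The combination with PFI-2 was examined to ask whether sites lost with GSK2879552 were present when SETD7 was inhibited too. Of the DMSO peaks without a GSK2879552 peak, 67.9% (67.3 to 68.5) overlapped a peak of the combination, as did 96.9% of those with a GSK2879552 peak (96.8 to 97.1). For 3 simulated libraries with unchanged sites, equal noise and the observed list lengths, the first share was 66.2% with 150000 candidate sites and 64.1% with 300000. The highest DMSO scores of this class were at chromosome 3 from 96431552 to 96432202 (708), chromosome X from 114383700 to 114384177 (630) and chromosome 10 from 126628563 to 126628983 (607), against 3636 for the highest DMSO score. In lists of 64217 peaks each, 6720 merged sites were found with DMSO and the combination only, 3186 with DMSO and GSK2879552 only, and 3979 with GSK2879552 and the combination only. The first count was 1.69 times the larger of the others, against 0.995 and 0.994 in the simulations with equal noise, which kept 74.1% and 75.0% of DMSO peaks with GSK2879552 where 71.2% were observed. With a noisier GSK2879552 library, set to keep as many DMSO peaks as observed, unchanged sites gave 1.50 and 1.77. With the combination list shortened to the length of the GSK2879552 list, the share present fell to 38.8%, while that list still overlapped 75.4% of all DMSO peaks, against 71.2% for the GSK2879552 list of the same length.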

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

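The alternatives without chromosomes 1, 3, 7, 8 and 12, with score and chromosome strata, and with a shortened combination list were chosen after seeing the data. Of the 51 alternatives run over 8 results, 43 moved the value out of the interval of the reported one and 8 did not. The 6 results that are shares of peaks cannot change sign; the loss and gain differences could, and kept theirs in all 16 of their alternatives. SETD7 peaks at vehicle FOXA1 peaks (5.86%) came to 2.01% with reciprocal 50% overlap, 3.85% with midpoints within 200 bp, 12% within 1 kb, 14.8% for the 5000 highest SETD7 scores, 7.89% with the shCTL list and 9.34% without the 5 chromosomes. Local shifts gave 0.653%, 1.21%, 7.75%, 2.30%, 2.84% and 1.52%. Under the same 3 overlap rules, then the higher-scoring 50% of each list, then equal-sized lists, FOXA1 peaks kept after knockdown (44.5%) came to 38.5%, 40.9%, 48.4%, 50.6% and 51.5%, and without the 5 chromosomes to 45.2%. DMSO peaks kept with GSK2879552 (71.2%) came to 67.3%, 70.8%, 73.0%, 71.6% and 81.4% in that order. The loss difference at SETD7 peaks (−26.6 points) was −21.5 with reciprocal overlap, −18.3 within 1 kb, −18.7 in the higher-scoring 50%, −17.1 with equal-sized lists and −19.5 without the 5 chromosomes. The gain difference (11.8 points) was 10.0, 9.84, 10.6, 9.32 and 7.60 there, 19.5 without score matching and 10.7 with score and chromosome strata. Lost DMSO peaks present with PFI-2 (67.9%) came to 69.1% within 1 kb, 71.3% in the higher-scoring 50%, 56.9% with equal-sized lists and 38.8% with the shortened combination list. Looser rules and shorter lists change these shares by construction; otherwise the cause was not tested. Alternatives without promoter peaks, and all those for promoters, motifs and gene lists, were not run for want of an hg19 annotation or sequence here. Depth, unknown here, limits every kept share.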

Other observations

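The tests chosen only after the result was seen were those of chromosome differences in LNCaP and of chromosomes 1, 3 and 8, that of SETD7 scores on the 5 chromosomes, the simulation with unequal noise, the window ratios without a shared list and their simulation, and the use of the higher-scoring 50% of peaks on chromosomes 3 and 8.

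FOXA1 sites were shared between the lines in part. Of the vehicle FOXA1 peaks of 22Rv1, 48.3% overlapped an LNCaP DMSO peak, and 91.8% did so in the highest decile of scores. In LNCaP, FOXA1 peaks found with GSK2879552 but not DMSO overlapped a 22Rv1 SETD7 peak in 4.38% of 6649 cases (3.91 to 4.90), against 1.02% of 57568 GSK2879552 peaks also found with DMSO (0.939 to 1.1). Of the DMSO peaks without a GSK2879552 peak, 0.320% overlapped a SETD7 peak. These classes were not matched by score, and the peaks found with GSK2879552 but not DMSO were mostly weak. In the highest decile of SETD7 scores, 16.6% overlapped a GSK2879552 peak and 10.7% a DMSO peak. Below it, no decile exceeded 2.04% and 2.08%, respectively. That highest decile includes the highest-scoring SETD7 sites, which were peaks in every list. A gain of FOXA1 at SETD7 sites with GSK2879552 was not tested. In the 22Rv1 libraries, chromosome 19 kept 63.8% of its shCTL FOXA1 peaks after SETD7 knockdown (61.5 to 66.1) and chromosome 13 kept 36.9% (35.1 to 38.8). These were the highest and lowest of 24 chromosomes. In the vehicle list the same chromosomes kept 45.9% and 52.2% of their shCTL peaks. In LNCaP they kept 75.7% and 67.1% of their DMSO peaks with GSK2879552, so the order was not particular to SETD7 knockdown.

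SETD7 peaks were concentrated on chromosomes 1, 3, 7, 8 and 12, and 22Rv1 peak numbers stepped along chromosomes 1, 3 and 8; LNCaP DMSO held 31.9% of its peaks on the 5 chromosomes on the same build, which argues against mappability. For background called as weak peaks, the lower-scoring 50% of the vehicle FOXA1 list was predicted to exceed the upper by more than 5 points. The excess was 1.75 points (0.998 to 2.50), so the prediction was not met, although the direction was the predicted one. It was 3.35 points (2.69 to 4.00) in the shCTL list and 8.43 (7.67 to 9.19) in the shSETD7 list, against −0.76 (−1.41 to −0.117) in LNCaP DMSO. The shSETD7 list thus exceeded 5 points, although the prediction was made for the vehicle list. A smaller part played by such background in the vehicle list, and a larger one in the shSETD7 list, are therefore not excluded. In the SETD7 list such background cannot be told apart from other causes. The highest decile of scores held 48.4% of its peaks on the 5 chromosomes (46.5 to 50.4), 23.8 points below the other deciles at 72.2% (71.6 to 72.7). The lowest decile held 57.1% (55.2 to 59.0), the lower-scoring 50% 67.7% and the upper 71.9%. A higher share in the lower-scoring 50% had been predicted too, and this was not met. That split cannot decide the question, because all deciles below the highest scored between 13 and 58. A gained segment of chromosome 1 is a candidate explanation, as vehicle FOXA1 peaks per Mb rose 1.79 times across the SETD7 boundary relative to LNCaP DMSO, and fewer copies of the first part of chromosome 3 in the shCTL cells may explain a log2 step of −0.55 against vehicle (−0.46 in the higher-scoring 50%), with DNA copy number not analysed here. On chromosome 8 the shSETD7 step against vehicle was −0.61 but −0.20 in the higher-scoring 50%, and the same ratio stepped further on chromosomes 13 (0.76) and 21 (−0.78), so a missing segment and other causes cannot be told apart there, and a regional effect of SETD7 on FOXA1 stays open and untested.

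Over windows of 10 Mb, the log2 ratio of shSETD7 to shCTL peaks in 22Rv1 ran with that of GSK2879552 to DMSO peaks in LNCaP. Here r was 0.57 and rho 0.58 over 300 windows, which are not independent replicates. Correlated ratios do not mean loss in the same windows. On chromosome 3 before 78 Mb, for example, the log2 ratio was 0.33 after knockdown and −0.28 with GSK2879552. For vehicle over shCTL in place of the knockdown, r was 0.14. For the combination over DMSO in place of GSK2879552 over DMSO, r was 0.24. In all, 18 such correlations were computed. A shorter list that drops the weak control peaks does not account for the 22Rv1 side: the shCTL list shortened to the shSETD7 length gave r = −0.36 outside the 5 chromosomes and −0.29 over all, where a value above 0.5 had been predicted, and −0.14 and −0.35 over all with vehicle replacing shCTL in 1 of the ratios. In LNCaP the same test gave r = 0.39, and 0.24 (0.18 without the 5 chromosomes) and 0.31 with the combination replacing DMSO in 1 of the ratios. Simulated unchanged libraries gave a mean of 0.0091 (−0.18 to 0.19 in 100 draws), with peaks drawn independently of score. Weak peaks could not gather in the same windows in that simulation, so it covers only the shared DMSO list and not list length. All observed values but the 0.18 lie between the bounds of 0.2 and 0.5, so list length cannot be told apart from other causes in LNCaP. Base composition was not tested without an hg19 sequence, and a shared effect of SETD7 loss and LSD1 inhibition was not tested and stays open.

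DMSO sites absent with GSK2879552 and present with PFI-2 added exceeded both mirror patterns in equal-sized lists, by 1.69 times the larger. This passed the bound of 1.2 set beforehand for a list that is shorter only through lower sensitivity. The bound had taken the libraries as equally noisy, and it was judged wrong only after the value was seen: unchanged sites simulated with a noisier GSK2879552 library gave 1.50 and 1.77 with 150000 and 300000 candidate sites, and 0.995 and 0.994 with equal noise. The simulation with the noisier library also gave 71.6% and 70.8% of lost DMSO peaks present in the combination, somewhat above the observed 67.9%, and its noise was fitted to these data. Lower sensitivity and a change of sites therefore cannot be told apart, and an effect of PFI-2 through SETD7 stays open and untested.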
